A study of Caenorhabditis elegans with 80 samples.

How the data were processed

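The values started from the expected counts per gene that the authors deposited for 80 libraries. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR 2.7.11b to the WBcel235 genome and counted per gene with RSEM 1.3.3, so a read that matches several genes is shared out among them by RSEM's model. The library preparation kit and the strandedness are not given in the sources used here. Of the values in the table, 2.73 percent were not whole, and all were rounded to whole counts. The table held 46904 genes, of which 23053 were at 0 in every library and 23763 had at least 1 rounded count. Symbols and WBcel235 coordinates came from the gene annotation, which gave a symbol for 44026 of the gene IDs.

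Libraries were grouped by the strain and age in their labels. The 36 N2 libraries at day 6 were kept as 2 sets, because 6 carry the day in their library name like the older ages and 30 do not, although the sample titles number these 30 on from the first 6, as 7 to 36. The 30 time-course libraries were fitted together with 1 coefficient per age. The 20 CF1038 libraries were fitted with the 30 N2 libraries of the second set, so the comparisons with age and with strain share no library. All libraries carry the same batch value, so no batch term was used.

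Each comparison used edgeR 4.0.16 with filterByExpr, TMM scaling, robust quasi-likelihood fits and a 2-sided quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Every adjusted p for a single gene comes from this edgeR test unless another tool is named. Log2 fold changes and their standard errors (SE) come from the same fits, the SE being the absolute log2 fold change divided by the square root of F. CPM are counts scaled by TMM to a library total of 1e+06, given as mean ± SD over libraries. The other software was R 4.3.3, limma 3.58.1, DESeq2 1.42.0, the data.table package in version 1.17.8, Python 3.11.15, matplotlib 3.10.9 and scipy 1.17.1.

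The named genes follow a rule. For day 18 and for CF1038, it took in each direction the 10 called genes with the largest absolute log2 fold change, a standard symbol, a mean of at least 10 CPM in the higher group, and at least 90 percent of the libraries of each group on their own side of the other group's median. It took 5 per direction at days 8, 11 and 14, and 3 per direction for successive ages and for the 2 N2 sets. It took the 5 with the smallest adjusted p in each direction for the linear trend, and up to 4 members with the smallest adjusted p for each gene list at day 18 and in CF1038. List members named at days 8, 11 and 14 are among those with the smallest adjusted p at that age and were picked after the values were seen.

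The 39 gene lists were fixed by symbol. They cover DAF-16 class I and class II genes, insulin signalling components, insulin-like peptides, vitellogenins, collagens, basement membrane, major sperm proteins, other sperm genes, germline and oocyte, cell cycle, zygotic embryo, histones, ribosomal proteins, and the nuclear and mitochondrial parts of the respiratory chain. They also cover heat shock proteins, organelle chaperones, oxidative stress, cytochromes P450, UDP-glucuronosyltransferases, glutathione S-transferases, C-type lectins, lysozymes and saposins, antimicrobial peptides, infection response, F-box and MATH genes, proteasome, autophagy and lysosome, lipid metabolism, carbon metabolism, muscle, pharynx, neurons, flp neuropeptides, intestine, hypodermis, other somatic tissues and splicing factors. Some genes stand on 2 lists, such as dod-22, ins-7, daf-28 and mlc-1. Lists were tested with camera on the edgeR counts with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison. The same test was run with an estimated correlation, and fry was run beside it. The gene counts of a list use the adjusted p over all tested genes, and counts adjusted over the list alone stand beside them.

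The spread between libraries of an age was measured per library as the root mean square deviation of its log2 CPM (prior count 2) from the mean of the other libraries of its group. Each older age was compared with day 6 by an exact 2-sided permutation test of the mean, adjusted over the 4 comparisons. Overlaps between comparisons were tested with Fisher's exact test across genes, which are not independent replicates. The grouping, tests, gene lists, named-gene rule and the first set of alternatives were chosen before the data were examined. The alternatives that use libraries 1 to 3 or 4 to 6, N2 libraries 21 to 30, libraries 1 to 10 or 11 to 20, a 2-level block, a covariate of library number, or leave out single libraries of the second set were chosen after seeing the data, as were the splits by library number.

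The edgeR, DESeq2, camera, spread and overlap steps were tested on simulated data. With 200 changed genes of 15732 at the size of the day 18 comparison, edgeR recovered 92 percent of 2-fold and 100 percent of 4-fold changes with 7 false calls, and DESeq2 recovered 93 and 100 percent with 17 false calls. The linear trend recovered 91 and 100 percent with 7 false calls, and the strain comparison 99 and 100 percent with 9. In camera, the 1 list of 39 that was raised was called and 0 others were. In the spread test, libraries simulated with SD 0.5 against 0.3 gave a ratio of 1.68 for a simulated 1.67 with an exact p of 0.00216, and 7 percent of 1000 sets simulated with no difference gave an exact p under 0.05, so the test calls slightly too often. The overlap of independent random calls gave exact p from 0.0250 to 0.965, 1 of 4 under 0.05. No pair of libraries in a group was a copy of another: the lowest chi-square per gene of 700 pairs was 7.55, where 1 is sampling noise.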

Results

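RNA from whole Caenorhabditis elegans worms was sequenced as paired reads of 150 nucleotides in 80 libraries. Worms of the wild-type strain N2 were collected at days 6, 8, 11, 14 and 18, with 6 libraries per age. CF1038 worms, which carry the daf-16 allele mu86, were collected at day 6 in 20 libraries, beside a second set of 30 N2 libraries at day 6. Worms were grown at 20 °C on streptomycin plates with OP50-1 bacteria, and FUDR, an inhibitor of DNA synthesis that stops the production of progeny, was used to keep the ages apart. The total count per library, in units of 1e+06, ran from 34.4 to 44.2 (37.5 ± 1.99, SD, n = 80), and 18651 to 20519 genes had a count in a library. Per group, the totals ran from 35.7 to 41 at day 6, 34.5 to 38.9 at day 8, 35.9 to 41 at day 11, 34.6 to 44.2 at day 14 and 36.4 to 39.1 at day 18. They ran from 34.7 to 41.2 in the second N2 set and from 34.4 to 42.7 in CF1038. Ribosomal RNA took 0.131 to 2.16 percent of a library. The labels do not say whether libraries came from separate cultures, so the p-values measure the spread between libraries.

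The gene daf-16 (WBGene00000912, WBcel235 chromosome I, 10750498 to 10776703) encodes the FOXO transcription factor that acts downstream of insulin signalling. In the day 6 libraries it stood at 94.1 ± 8.42 CPM in CF1038 (SD, n = 20, range 75.5 to 107) and at 165 ± 15.1 CPM in the second N2 set (SD, n = 30, range 134 to 191). Each of the 20 CF1038 libraries lay below each N2 library, with a log2 fold change of -0.81 (SE 0.04, adjusted p = 2.8e-23). Counts cover the whole gene, so they do not separate the part that mu86 deletes from the part that remains. In the time course daf-16 stood at 162.5 ± 16 CPM at day 6 and 167 ± 12 at day 8, a difference that did not pass (adjusted p = 0.777). It rose by log2 0.32 at day 11 (202 ± 8.88 CPM, adjusted p = 0.00116), 0.29 at day 14 (198 ± 19.3 CPM, adjusted p = 0.00183) and 0.21 at day 18 (188 ± 15.2 CPM, adjusted p = 0.0166).

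**Figure D1:**
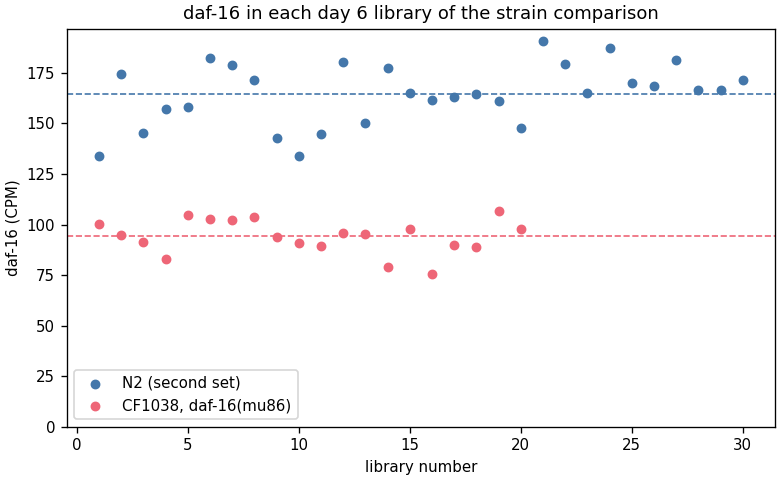
CPM of daf-16 (y axis) in each day 6 library of the strain comparison, by library number (x axis), with dashed lines at the group means. The 20 CF1038 libraries lie between 75.5 and 107 CPM, and the 30 N2 libraries between 134 and 191 CPM.

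In a principal component analysis of the 30 time-course libraries, component 1 took 65.2 percent of the variance and ordered the ages from day 6 and day 8 to day 18. Component 2 took 10.5 percent and parted libraries 1 to 3 from libraries 4 to 6 at days 14 and 18, and component 1 also parted them at day 18.

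**Figure D2:**
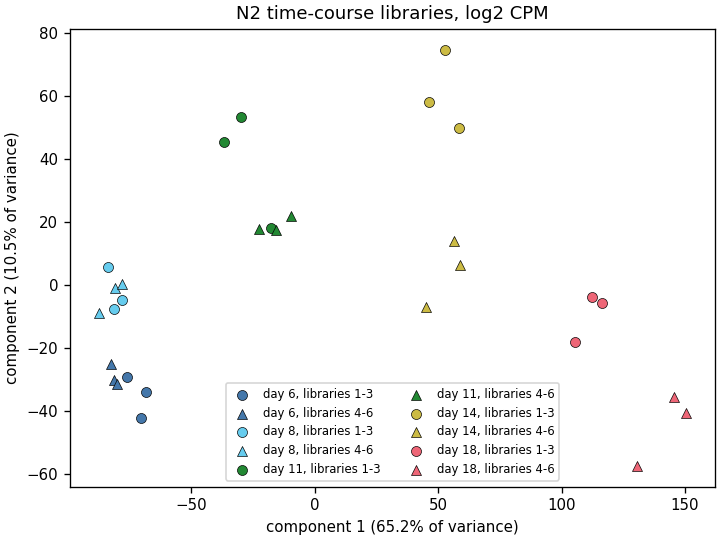
The 30 time-course libraries on the first 2 principal components of log2 CPM over 16710 genes (x axis, 65.2 percent of the variance; y axis, 10.5 percent). Colours give the age, circles libraries 1 to 3 and triangles libraries 4 to 6, which lie apart at days 14 and 18.

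The widest comparison with age set day 18 against day 6, with n = 6 per age. The sperm chromatin gene spch-3 (WBGene00020840, chromosome I, 6098927 to 6099731) rose 180-fold, from 1.48 ± 0.826 to 267 ± 112.45 CPM (log2 7.49, SE 0.37, adjusted p = 1.9e-16), and the sperm peptide gene nspd-10 rose 313-fold, from 0.0525 ± 0.0236 to 17.4 ± 6.95 CPM. Among the genes that fell, the cuticle collagen col-92 (chromosome III, 10982139 to 10983253) dropped from 14.3 ± 4.36 to 0.0260 ± 0.0285 CPM, and the yolk protein gene vit-6 dropped 3.85-fold (log2 -1.95, SE 0.17, adjusted p = 2.2e-11). In all, 9519 of 16710 tested genes changed, 4840 higher and 4679 lower, and 2359 and 1938 of these by at least 2-fold.

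Among the genes with the largest rise, msrp-3 (log2 9.17, 14.4 ± 6.21 CPM at day 18), msrp-6 (7.57), ttbk-2.1 (8.45), rnh-1.1, of the RNase H family (7.99), nsph-4.2 (7.50), nsph-4.1 (7.45) and the acyl-CoA synthetase gene acs-18 (7.68) were each under 1 CPM at day 6. The saposin-like gene spp-9 rose from 0.136 ± 0.127 to 73.4 ± 51.4 CPM (log2 9.09, SE 0.77). The largest falls beside col-92 under the named-gene rule were those of the collagens col-17 (log2 -7.30), col-117 (-7.20) and col-167 (-6.90), the C-type lectin clec-209 (-7.04, 103.7 ± 35.5 CPM at day 6), nspc-17 (-7.42), nspc-18 (-6.93), vmo-1 (-6.67, 18.2 ± 6.96 CPM at day 6) and dod-21 (-6.66, 13.1 ± 15.2 CPM at day 6). At day 18, col-117 was at 0 in 5 of 6 libraries, so the size of its fold rests on 1 library, although all 6 lay below every day 6 library. The symbol clec-209 belongs to 2 gene IDs with identical counts, and close copies such as nspc and msp genes share reads, so their single values are uncertain.

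Of the 28 major sperm protein genes tested, which encode the motility and signalling protein of nematode sperm, all 28 rose (28 adjusted over the list alone, median log2 6.26). The examples msp-38, msp-77 and msp-59 reached 26.1 ± 8.52, 58.9 ± 14.5 and 96.1 ± 37.4 CPM. Other sperm genes gave 56 that rose, 1 that fell and 2 that did not pass out of 59, or 57 and 1 adjusted over the list alone (median 4.90), among them spe-18 (log2 4.94) and the phosphatase gene gsp-4 (6.48). In camera the lists had adjusted p = 1.7e-31 and 2.2e-39, and with an estimated correlation adjusted p = 0.0955 and 0.0419, so of the 39 lists at day 18 the other sperm genes alone kept their call. The summed level of the major sperm protein genes went from 19.4 ± 9.61 CPM at day 6 through 7.21 ± 2.21 at day 8, 44.4 ± 17.8 at day 11 and 398 ± 84.4 at day 14 to 1288 ± 432 at day 18. Histone genes also moved up: 46 rose, 3 fell and 17 did not pass out of 66 (46 and 3 adjusted over the list alone), with the linker histone gene hil-2 at 149 ± 19.6 against 40.2 ± 12.8 CPM and the H3 gene his-70 higher by log2 6.13. The median was 1.00, with camera adjusted p = 0.00218 and adjusted p = 0.641 with an estimated correlation. The summed level of the histone genes was 2108 ± 151 CPM at day 18 against 1839 ± 118 at day 6 (SD, n = 6 per age). In the second N2 set at day 6 it was 2189 ± 272 CPM (SD, n = 30), so the sum does not show the rise of the median.

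Of 40 muscle structural genes 33 fell, 1 rose and 6 did not pass (34 and 1 adjusted over the list alone). Its median log2 fold change was -0.77, with camera adjusted p = 3.9e-09 and adjusted p = 0.586 with an estimated correlation, and it was -1.19 in libraries 4 to 6. The troponin T gene tnt-2 went from 197 ± 31.6 to 15.1 ± 6.02 CPM and the myosin light chain gene mlc-2 from 312 ± 37 to 56.3 ± 16.8 CPM. Of 33 intestinal genes 26 fell, 1 rose and 6 did not pass (26 and 1 adjusted over the list alone), including the intermediate filament gene ifc-1 (log2 -5.60) and the aquaporin gene aqp-4 (-3.40). Their summed level at day 18 was 3460 ± 285 CPM in libraries 1 to 3 and 1701 ± 256 CPM in libraries 4 to 6 (SD, n = 3). This list had a median of -1.06, and -0.62 in libraries 1 to 3, with camera adjusted p = 3.5e-07 and adjusted p = 0.586 with an estimated correlation. Collagens gave 92 that fell, 25 that rose and 38 that did not pass out of 155, or 94 and 25 adjusted over the list alone, and col-160 went from 456 ± 116 to 16.8 ± 7.37 CPM. Over the list the median was -0.99, and -1.66 with all 36 controls, with camera adjusted p = 1.6e-09 and adjusted p = 0.398 with an estimated correlation. Vitellogenins gave 5 of 6 that fell and 1 that did not pass (5 adjusted over the list alone), and their summed level was 28506 ± 5753 CPM at day 18 against 72582 ± 11265 at day 6. Here the median stood at -1.97, and -1.27 in libraries 1 to 3, with camera adjusted p = 0.00172 and adjusted p = 0.586 with an estimated correlation.

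C-type lectins gave 96 that fell, 25 that rose and 30 that did not pass out of 151 (97 and 27 adjusted over the list alone), and clec-73 (log2 4.85) and clec-123 (5.04) went up. Across members the median was -1.21, with camera adjusted p = 4.9e-06 and adjusted p = 0.525 with an estimated correlation. UDP-glucuronosyltransferases gave 37 lower, 7 higher and 19 not passed out of 63 (37 and 8 adjusted over the list alone), with ugt-43 down by log2 -5.90 and ugt-53 by -4.80. For this list the median was -0.69, and -0.41 in libraries 1 to 3, with camera adjusted p = 2.3e-04 and adjusted p = 0.665 with an estimated correlation. For cytochromes P450 the counts were 35 lower, 9 higher and 24 not passed out of 68, unchanged when adjusted over the list alone, and cyp-14A5 rose from 129 ± 19.4 to 563 ± 145 CPM while cyp-13A5 fell by log2 -2.76. A median of -0.54 went with camera adjusted p = 8.6e-04 and adjusted p = 0.641 with an estimated correlation. Glutathione S-transferases gave 23 lower, 4 higher and 17 not passed out of 44 (23 and 5 adjusted over the list alone), with gst-28 down by log2 -3.35. The median was -0.65, with camera adjusted p = 0.00167 and adjusted p = 0.641 with an estimated correlation. Lysozymes and saposins gave 17 lower, 7 higher and 13 not passed out of 37 (18 and 7 adjusted over the list alone), ilys-5 falling from 292 ± 87 to 14.2 ± 4.58 CPM. Its median log2 fold change was -0.70, with camera adjusted p = 0.0168 and adjusted p = 0.752 with an estimated correlation. In libraries 1 to 3 it was -0.21 with 14 lower, and in libraries 4 to 6 it was -1.36 with 22 lower. F-box and MATH genes gave 161 lower, 74 higher and the others not passed out of 357 (161 and 78 adjusted over the list alone), although fbxa-218 and fbxa-202 rose by log2 3.79 and 6.30. This list had a median of -0.40, with camera adjusted p = 0.0236 and adjusted p = 0.681 with an estimated correlation.

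The flp neuropeptide genes gave 25 that fell and 5 that did not pass out of 30 (25 adjusted over the list alone), with flp-26 at log2 -1.74 and flp-27 at -1.42. Over the list the median was -0.90, with camera adjusted p = 3.2e-05 and adjusted p = 0.641 with an estimated correlation. Autophagy and lysosome genes gave 42 lower, 10 higher and 27 not passed out of 79, with the same counts adjusted over the list alone. Here the median stood at -0.30, and -0.46 in libraries 4 to 6, with camera adjusted p = 2.7e-04 and adjusted p = 0.398 with an estimated correlation. The protease genes asp-14 and asp-8 fell by log2 -5.53 and -5.77, and sqst-1, the p62 homologue that binds autophagy cargo, rose from 190 ± 9.31 to 363 ± 17 CPM. Of 22 zygotic embryo genes 15 fell, 2 rose and 5 did not pass (15 and 2 adjusted over the list alone), among them hnd-1 (log2 -2.1). Across members the median was -0.97, with camera adjusted p = 0.00543 and adjusted p = 0.641 with an estimated correlation. The DAF-16 class II genes, which are lower when DAF-16 is active, gave 11 lower, 1 higher and 5 not passed out of 17, also adjusted over the list alone. For this list the median was -1.12, with camera adjusted p = 0.00641 and adjusted p = 0.586 with an estimated correlation. It was -0.71 in libraries 1 to 3 and -0.70 with all 36 controls. In that list dod-17 fell by log2 -5.98, dod-24 by -3.08 and dod-22 by -3.45, while the insulin-like peptide gene ins-7 rose from 4.67 ± 1.38 to 35.4 ± 14.3 CPM. Pharyngeal genes gave 13 lower, 2 higher and 11 not passed out of 26, also adjusted over the list alone, with mlc-1 at log2 -1.86. A median of -0.58 went with camera adjusted p = 0.0219 and adjusted p = 0.665 with an estimated correlation. It was -0.21 with the 12 libraries alone (4 higher and 10 lower of 23) and -1.83 with all 36 controls (2 and 18 of 30).

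The camera test did not pass at day 18 for the other 21 lists, in which single genes still changed. Organelle chaperones had 12 that rose and 11 that did not pass out of 23 (camera adjusted p = 0.105), among them enpl-1, the GRP94 homologue, at 823 ± 57.6 against 455 ± 48.4 CPM. Ribosomal proteins had 29 higher and 3 lower of 81 (adjusted p = 0.291), with rps-6 up by log2 0.77. Lipid metabolism had 29 higher and 43 lower of 103 (adjusted p = 0.316), acs-10 rising by log2 6.26. The nuclear part of the respiratory chain had 4 higher and 17 lower of 64 (adjusted p = 0.144, median -0.10 and mean 0.01), with cyc-2.2, a cytochrome c gene, up by log2 6.56. The mitochondrially encoded part had 0 higher and 5 lower of 12 (adjusted p = 0.176), but 4 higher and 0 lower in libraries 1 to 3 (median 0.17) and 0 higher and 12 lower in libraries 4 to 6 (median -1.12), and 1 and 5 with all 36 controls (median -0.15). Carbon metabolism had 7 higher and 18 lower of 43 (adjusted p = 0.169). Proteasome genes had 1 higher and 6 lower of 31 (adjusted p = 0.242), 1 and 1 with RLE size factors or DESeq2, 2 and 0 in libraries 4 to 6, and 6 and 1 with all 36 controls (median 0.04). Heat shock genes had 1 higher and 9 lower of 24 (adjusted p = 0.144, median -0.16), and 3 and 16 of 25 with all 36 controls (median -0.96). The counts were 6 and 10 of 35 for oxidative stress (adjusted p = 0.23) and 8 and 17 of 68 for splicing (adjusted p = 0.169). Germline and oocyte genes had 11 higher and 25 lower of 53 (adjusted p = 0.0841), or 15 and 19 with all 36 controls, cell cycle 3 and 10 of 33 (adjusted p = 0.303) and basement membrane 0 and 5 of 17 (adjusted p = 0.1), or 4 and 3 in libraries 1 to 3. Hypodermal genes had 7 higher and 9 lower of 30 (adjusted p = 0.166, median -0.13), and 7 and 19 of 32 with all 36 controls (median -1.07). Neurons had 10 and 15 of 49 (adjusted p = 0.169, median -0.25), and 5 and 26 with all 36 controls (median -0.40). Other somatic tissues had 9 and 4 of 21 (adjusted p = 0.586). DAF-16 class I genes, which are higher when DAF-16 is active, had 6 higher and 9 lower of 27 (adjusted p = 0.527, median -0.08, and -0.46 with all 36 controls), with lys-7 at 3383 ± 1477 against 556 ± 135 CPM and ftn-1 up by log2 1.90 while cyp-34A9 went down by -2.50. Summed over this list, the level was 6501 ± 1569 CPM at day 18 against 4223 ± 415 at day 6 (SD, n = 6 per age). This sum holds lys-7 at 3383 ± 1477 against 556 ± 135 CPM, so it does not show a rise of the list. Insulin-like peptides had 6 higher and 14 lower of 30 (adjusted p = 0.2), insulin signalling components 5 and 1 of 25 (adjusted p = 0.862, median 0.07 with the test downward) and antimicrobial peptides 13 and 13 of 36 (adjusted p = 0.586), or 12 and 21 of 42 with all 36 controls. Infection response genes had 29 higher and 20 lower of 57 with a median of 0.45 while camera pointed down (adjusted p = 0.883), and 18 higher and 23 lower of 58 with all 36 controls (median 0.07). Examples are pals-26 rising by log2 1.60 and irg-8 going from 248 ± 96.7 to 18.4 ± 10.6 CPM.

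**Figure D3:**
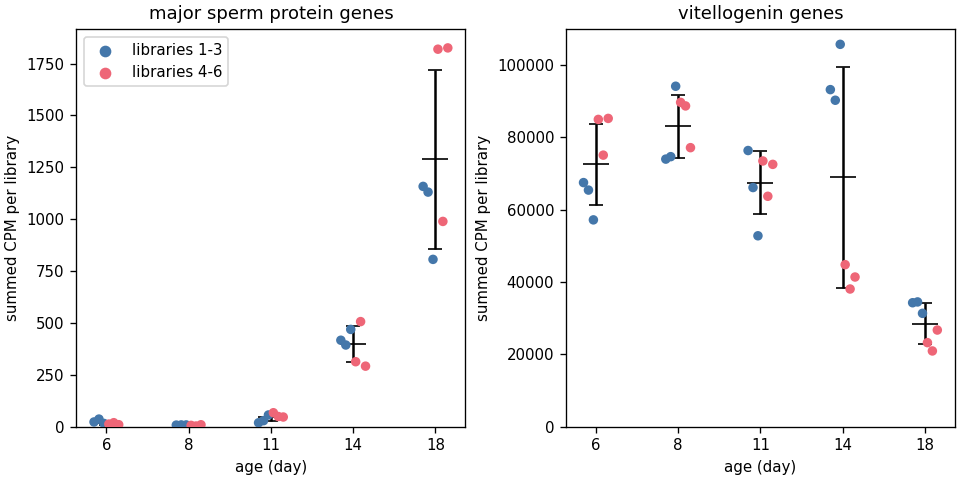
Summed CPM per library (y axis) of the major sperm protein genes and the vitellogenin genes by age in days (x axis). Points are libraries, long bars the means and error bars the SD of 6 libraries, and at day 14 the vitellogenin sum was 96419 ± 8212 CPM in libraries 1 to 3 against 41426 ± 3367 in libraries 4 to 6.

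By day 8 fewer genes had changed from day 6, and the largest falls among the named genes were in collagens. The collagen col-147 dropped from 22 ± 17.3 to 1.07 ± 0.364 CPM (log2 -4.35, SE 0.41, adjusted p = 8.1e-08, n = 6 per age), and col-17 (-4.20), col-117 (-4.03), col-167 (-3.87) and dpy-5 (-3.78), a cuticle procollagen gene, followed. The collagen col-183 rose from 13.1 ± 8.80 to 58.3 ± 21.8 CPM (log2 2.15, SE 0.31, adjusted p = 3.6e-05), and lips-11, of the lipase family, rose by log2 2.28. Others with a large rise were cld-1 (log2 3.54), dod-21 (2.87) and irg-6 (2.06), and in cld-1 and dod-21 the value of day 8 library 5, at 251 and 320 CPM, stood far above the rest. In all, 1950 genes changed, 928 higher and 1022 lower.

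Collagens gave 62 lower, 8 higher and 85 not passed out of 155 at day 8 (69 and 11 adjusted over the list alone). The median was -0.52, with camera adjusted p = 2.1e-18 and adjusted p = 0.153 with an estimated correlation. The summed level of the collagens ran the other way, at 32764 ± 3017 CPM against 26337 ± 3984 at day 6 (SD, n = 6 per age), and was not tested. The 28 major sperm protein genes gave 18 lower and 10 not passed (23 adjusted over the list alone), from levels near 1 CPM such as msp-19 at 1.18 ± 0.815 CPM at day 6. Its median log2 fold change was -1.54, with camera adjusted p = 4.5e-16 and adjusted p = 0.508 with an estimated correlation. Other sperm genes gave 12 lower, 1 higher and 46 not passed (17 and 4 adjusted over the list alone). This list had a median of -0.43, with camera adjusted p = 0.00439 and adjusted p = 0.941 with an estimated correlation. Pharyngeal genes gave 7 lower and 19 not passed (9 adjusted over the list alone, median -0.41, camera adjusted p = 4.6e-05, adjusted p = 0.508 with an estimated correlation). Autophagy and lysosome genes gave 10 higher, 2 lower and 67 not passed (12 and 2 adjusted over the list alone, median 0.14, camera adjusted p = 2.6e-04, adjusted p = 0.508 with an estimated correlation). Of the pharyngeal genes abu-14 fell by log2 -1.69, and of the autophagy genes sqst-1 rose to 290 ± 13.9 CPM. Infection response genes gave 7 higher, 1 lower and 49 not passed (10 and 4 adjusted over the list alone, median 0.28, camera adjusted p = 0.0155, adjusted p = 0.941 with an estimated correlation), with dod-24 up by log2 1.34. The basement membrane list gave 2 higher and 15 not passed (5 adjusted over the list alone, median 0.34, camera adjusted p = 0.00486, adjusted p = 0.941 with an estimated correlation). The nuclear respiratory chain gave 6 lower and 58 not passed (5 adjusted over the list alone, median -0.11, camera adjusted p = 0.00362, adjusted p = 0.941 with an estimated correlation). Splicing gave 9 lower and 59 not passed (9 adjusted over the list alone, median -0.10, camera adjusted p = 0.00606, adjusted p = 0.941 with an estimated correlation). Other somatic tissues gave 5 higher and 16 not passed (5 adjusted over the list alone). Over the list the median was 0.11, with camera adjusted p = 0.0356 and adjusted p = 0.508 with an estimated correlation. The count of changed genes was 3805 with the 12 libraries of the 2 ages alone, 3837 with libraries 1 to 3, 523 with libraries 4 to 6 and 7979 with all 36 N2 day 6 libraries as controls. The lists of day 8 were not refitted with other controls or subsets of libraries.

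At day 11, 7338 genes had changed from day 6, 4020 higher and 3318 lower. The saposin-like gene spp-9 rose 87.1-fold to 11.8 ± 3.39 CPM, lact-6 rose 54.7-fold to 16.9 ± 2.51 CPM (log2 5.77, SE 0.47, adjusted p = 2.2e-10, n = 6 per age), and col-183 rose 29.8-fold to 391 ± 89.1 CPM. The saposin-like gene spp-12 (log2 4.73) and the DAF-16 class I gene dod-3 (4.41, 150.5 ± 33.8 CPM) also rose. Among the genes that meet the named-gene rule, the cuticle genes col-17 (log2 -5.65), col-147 (-4.82), dpy-13 (-4.10), dpy-5 (-4.10) and col-92 (-4.07) fell furthest.

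Among the lists at day 11, DAF-16 class I genes gave 16 higher, 2 lower and 9 not passed out of 27 (16 and 3 adjusted over the list alone, median 0.69, camera adjusted p = 2.6e-04, adjusted p = 0.555 with an estimated correlation). The lysozyme gene lys-7 stood at 5979 ± 1349 against 556 ± 135 CPM, and the desaturase gene fat-7 was lower by log2 -2.86. Infection response genes gave 29 higher, 3 lower and 25 not passed (29 and 3 adjusted over the list alone, median 0.47, camera adjusted p = 9.5e-05, adjusted p = 0.555 with an estimated correlation), with thn-2 up by log2 3.15. Collagens gave 73 lower, 21 higher and 61 not passed (75 and 23 adjusted over the list alone, median -0.55, camera adjusted p = 1.1e-08, adjusted p = 0.555 with an estimated correlation). The summed level of the collagens did not fall, at 31579 ± 4209 CPM against 26337 ± 3984 at day 6 (SD, n = 6 per age). The nuclear respiratory chain gave 50 lower, 1 higher and 13 not passed (55 and 1 adjusted over the list alone, median -0.40, camera adjusted p = 2.8e-13, adjusted p = 0.555 with an estimated correlation). Embryo genes gave 17 lower, 3 higher and 2 not passed (17 and 3 adjusted over the list alone, median -1.09, camera adjusted p = 1.1e-04, adjusted p = 0.555 with an estimated correlation). Examples are ndus-8 at log2 -0.67 and hnd-1 at -1.34. Other somatic tissues gave 11 higher and 10 not passed (11 adjusted over the list alone, median 0.37, camera adjusted p = 0.0288, adjusted p = 0.555 with an estimated correlation). Proteasome genes gave 25 lower and 6 not passed (27 adjusted over the list alone, median -0.28, camera adjusted p = 1.4e-06, adjusted p = 0.779 with an estimated correlation). Splicing factors gave 33 lower, 4 higher and 31 not passed (36 and 4 adjusted over the list alone, median -0.25, camera adjusted p = 8.6e-06, adjusted p = 0.779 with an estimated correlation). Major sperm proteins gave 25 higher and 3 not passed (25 adjusted over the list alone, median 1.36, camera adjusted p = 4.0e-06, adjusted p = 0.779 with an estimated correlation). Other sperm genes gave 32 higher and 27 not passed (32 adjusted over the list alone). Here the median stood at 0.98, with camera adjusted p = 4.0e-06 and adjusted p = 0.717 with an estimated correlation. Antimicrobial peptides gave 21 higher, 3 lower and 12 not passed (22 and 3 adjusted over the list alone, median 0.76, camera adjusted p = 0.00114, adjusted p = 0.904 with an estimated correlation). Neuronal genes gave 21 higher, 1 lower and 27 not passed (24 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.0175, adjusted p = 0.904 with an estimated correlation). Germline genes gave 14 lower, 1 higher and 38 not passed (14 and 1 adjusted over the list alone, median -0.13, camera adjusted p = 0.00975, adjusted p = 0.904 with an estimated correlation). F-box and MATH genes gave 101 lower, 55 higher and 201 not passed (the same adjusted over the list alone, median -0.20, camera adjusted p = 0.0288, adjusted p = 0.904 with an estimated correlation). The mitochondrial respiratory chain gave 5 lower and 7 not passed (7 adjusted over the list alone, median -0.53, camera adjusted p = 0.0431, adjusted p = 0.904 with an estimated correlation). Pharyngeal genes gave 9 lower, 2 higher and 15 not passed (9 and 1 adjusted over the list alone). Across members the median was -0.27, with camera adjusted p = 0.0166 and adjusted p = 0.902 with an estimated correlation. The count of changed genes was 4557 with libraries 4 to 6 alone.

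At day 14, 9477 genes differed from day 6, 4986 higher and 4491 lower. The largest rises under the named-gene rule were those of spp-9, 824-fold to 111 ± 85.2 CPM (log2 9.69, SE 0.78, adjusted p = 3.6e-11, n = 6 per age), spp-12 (log2 6.83), nsph-4.1 (5.59) and the PDZ domain genes gipc-1 (5.53, 48.8 ± 6.94 CPM) and gipc-2 (5.52, 44.4 ± 8.43 CPM). Among the genes that meet the named-gene rule, the collagens col-92 (log2 -6.33), col-17 (-6.15), col-167 (-5.82) and col-147 (-5.73) and the gene nspc-17 (-5.27) fell furthest. All 28 major sperm protein genes rose (28 adjusted over the list alone, median 4.5, camera adjusted p = 1.6e-30, adjusted p = 0.0923 with an estimated correlation). Other sperm genes gave 53 higher, 1 lower and 5 not passed (53 and 1 adjusted over the list alone, median 3.08, camera adjusted p = 7.2e-27, adjusted p = 0.0923 with an estimated correlation).

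At day 14 libraries 1 to 3 and 4 to 6 were also fitted apart, each against the day 6 libraries of the same numbers, and the difference between the 2 fits was not tested. Proteasome genes gave 28 lower and 3 not passed out of 31 over all libraries (28 adjusted over the list alone, median -0.33, camera adjusted p = 5.3e-05, adjusted p = 0.92 with an estimated correlation), with 31 lower in libraries 1 to 3, 8 in libraries 4 to 6, and 19 with all 36 controls (median -0.18). Cell cycle genes gave 18 lower and 15 not passed out of 33 (20 adjusted over the list alone, median -0.35, camera adjusted p = 0.0017, adjusted p = 0.92 with an estimated correlation), with 31 and 3 lower in those subsets. Germline genes gave 34 lower, 2 higher and 17 not passed (35 and 2 adjusted over the list alone, median -0.38, camera adjusted p = 7.9e-05, adjusted p = 0.92 with an estimated correlation), with 43 and 16 lower, and 20 with all 36 controls (median -0.17). Splicing factors gave 45 lower, 5 higher and 18 not passed (48 and 5 adjusted over the list alone, median -0.31, camera adjusted p = 1.0e-05, adjusted p = 0.92 with an estimated correlation), with 53 and 20 lower. Muscle genes gave 16 lower, 1 higher and 23 not passed (16 and 1 adjusted over the list alone), with a median of 0.00 in libraries 1 to 3 and -0.68 in libraries 4 to 6. For this list the median was -0.30, with camera adjusted p = 0.00571 and adjusted p = 0.92 with an estimated correlation. Intestinal genes, whose test did not pass, had a median of 0.47 in libraries 1 to 3 and -0.68 in libraries 4 to 6. DAF-16 class I genes gave 16 higher, 2 lower and 9 not passed (16 and 2 adjusted over the list alone, median 0.68, camera adjusted p = 0.041, adjusted p = 0.92 with an estimated correlation), lys-7 reaching 8767 ± 3463 CPM. With all 36 controls 13 were higher and 7 lower of 28 (median 0.31). Infection response genes gave 30 higher, 4 lower and 23 not passed (30 and 4 adjusted over the list alone, median 0.62, camera adjusted p = 0.00446, adjusted p = 0.92 with an estimated correlation), with 34 and 24 higher in the subsets. Collagens gave 82 lower, 25 higher and 48 not passed (83 and 27 adjusted over the list alone, median -0.84, camera adjusted p = 2.0e-06, adjusted p = 0.891 with an estimated correlation), with 90 and 62 lower in the subsets. The summed level of the collagens did not fall, at 33548 ± 7477 CPM against 26337 ± 3984 at day 6 (SD, n = 6 per age). In the subsets of day 14 it was 37265 ± 1773 and 29831 ± 9756 CPM. The nuclear respiratory chain gave 44 lower, 1 higher and 19 not passed (44 and 1 adjusted over the list alone, median -0.38, camera adjusted p = 3.9e-08, adjusted p = 0.891 with an estimated correlation), with 57 and 30 lower. Embryo genes gave 17 lower, 3 higher and 2 not passed (18 and 3 adjusted over the list alone, median -1.16, camera adjusted p = 7.0e-04, adjusted p = 0.891 with an estimated correlation). In libraries 1 to 3 their median was -2.07 with 18 lower, and in libraries 4 to 6 it was -0.53 with 8 lower.

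**Figure D4:**
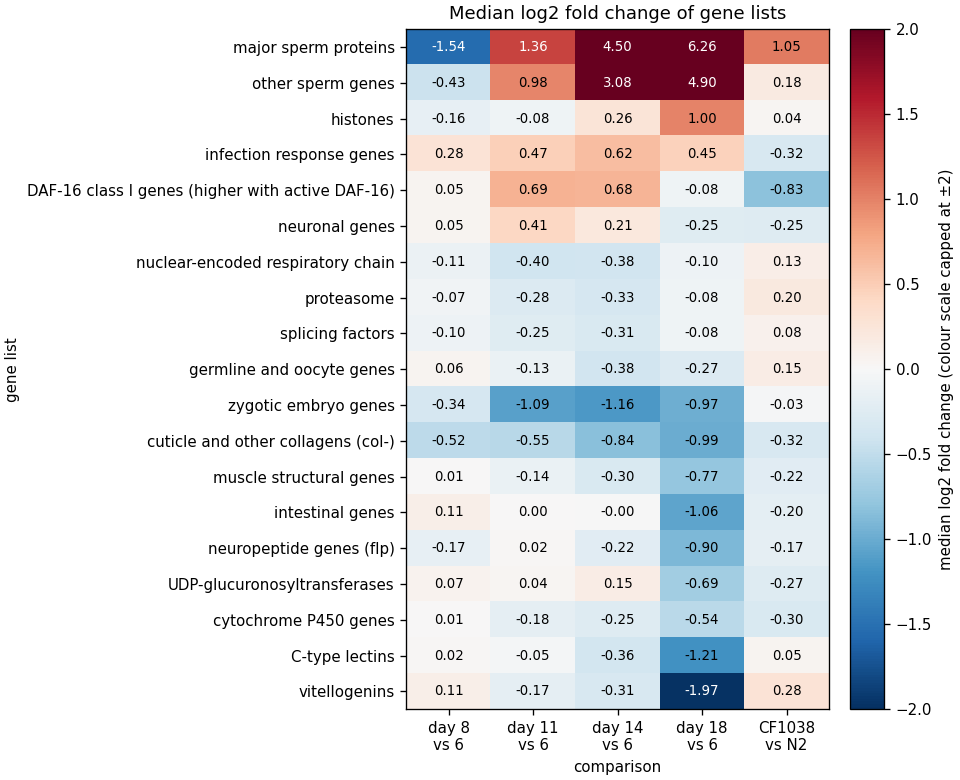
Median log2 fold change over the tested members of 19 gene lists (y axis) in 5 comparisons (x axis), with the colour scale capped at 2 in either direction. Major sperm proteins go from -1.54 at day 8 to 6.26 at day 18, vitellogenins stand at -1.97 at day 18, and DAF-16 class I genes are at 0.69 and 0.68 at days 11 and 14 and at -0.83 in CF1038, while the CF1038 values of collagens and neuronal genes turn positive with N2 libraries 21 to 30 as controls (0.26 and 0.02).

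Between successive ages, 4951 genes changed from day 8 to day 11 (3004 higher), 2443 from day 11 to day 14 (1687 higher) and 8520 from day 14 to day 18 (4598 higher). From day 8 to day 11, spp-9 (log2 5.29), lact-6 (4.63) and the dehydrogenase gene dhs-26 (4.63, 0.614 ± 0.175 to 15.2 ± 8.79 CPM) rose, and dod-17 (-3.50), ugt-43 (-3.31) and dod-21 (-3.06) fell. From day 11 to day 14 the sperm protein genes msp-53 (log2 3.57, SE 0.36, adjusted p = 9.3e-09, 22.4 ± 4.16 CPM at day 14, n = 6), msp-19 (3.35) and msp-33 (3.33) rose, and pud-2.2 (-2.45), pud-1.2 (-2.39) and dod-21 (-2.19) fell. From day 14 to day 18, acs-18 (log2 2.51), msrp-3 (2.30) and ubxn-5 (2.24) rose, and pcp-2 (-3.72, 15.2 ± 8.34 to 1.15 ± 0.836 CPM), clec-66 (-3.39) and oac-32 (-3.38) fell. The count from day 11 to day 14 was 1494 with the 12 libraries alone and 6131 with libraries 1 to 3, and that from day 8 to day 11 was 2336 with libraries 4 to 6.

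A linear trend over days was called for 8999 genes, 4670 rising and 4329 falling. The adenine nucleotide translocator gene ant-1.4 rose by log2 0.61 per day (SE 0.02, adjusted p = 1.6e-21), from 0.198 ± 0.0794 CPM at day 6 to 28 ± 7.79 at day 18 (n = 6 per age). The phosphatase gene ptp-5.3 (0.62 per day), spc-2 (0.43) and the sperm genes smz-1 (0.49) and smz-2 (0.35) also rose, and col-92 (-0.77 per day), nspc-17 (-0.64), vmo-1 (-0.57), nspc-16 (-0.50) and col-139 (-0.40) fell.

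**Figure D5:**
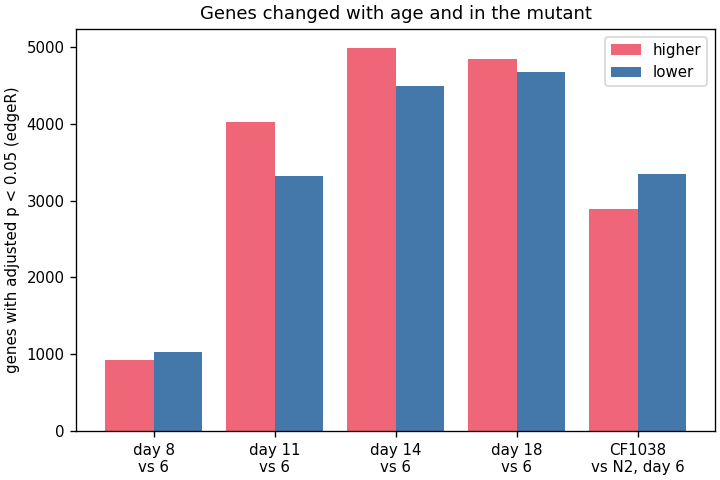
Number of genes (y axis, from 0) with an adjusted p under 0.05 in edgeR, higher and lower, in the comparisons of days 8, 11, 14 and 18 with day 6 and of CF1038 with N2 (x axis). The counts go from 928 higher and 1022 lower at day 8 to 4840 and 4679 at day 18, and the CF1038 bars stand at 2897 and 3341.

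Libraries of day 14 lay further apart than those of day 6. Their deviation from the mean of the others was 0.532 ± 0.0957 on the log2 scale against 0.403 ± 0.0460 (SD, n = 6, exact permutation p = 0.0173, adjusted over 4 ages p = 0.0693), above the day 6 mean in 6 of 6 libraries. The difference did not pass after adjustment. Within libraries 1 to 3 of day 14 it was 0.413 ± 0.0344 and within libraries 4 to 6 it was 0.531 ± 0.0570, against 0.396 ± 0.0462 and 0.429 ± 0.0235 at day 6. The differences of days 8, 11 and 18 from day 6 were -0.00117, 0.0143 and 0.0165 (adjusted exact p = 0.963, 0.739 and 0.739).

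The strain comparison set CF1038, which carries daf-16(mu86), against N2 at day 6, with n = 20 and n = 30. Of 27 DAF-16 class I genes tested, 19 were lower in the mutant, among them dod-3 by 8.21-fold (2.22 ± 0.493 against 18.3 ± 5.74 CPM, log2 -3.04, SE 0.13, adjusted p = 8.9e-26), the metallothionein gene mtl-1 by 7.94-fold, the ferritin gene ftn-1 by 7.74-fold and the superoxide dismutase gene sod-3 by 6.94-fold. The collagen col-183 (WBGene00000756, chromosome X, 13466643 to 13467764) was 34.7-fold lower, at 0.564 ± 0.274 against 19.6 ± 7.51 CPM. The cathepsin B-like protease gene cpr-5 was 2.82-fold higher (93.5 ± 34.1 against 33.2 ± 8.49 CPM), and the cilium gene dyf-3 2.23-fold higher in 20 of 20 libraries than in any N2 library. In all, 6238 of 16126 tested genes differed, 2897 higher and 3341 lower, with a median absolute log2 fold change of 0.29, and 132 and 270 by at least 2-fold.

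Further genes that were lower were the saposin-like gene spp-27 (log2 -4.09), the lectin gene clec-15 (-4.01), the esterase gene cest-1.1 (-3.91), the lysozyme gene ilys-3 (-3.41), fipr-24 (-3.28) and bgal-2 (-2.73). The N2 levels of spp-27, clec-15, ilys-3 and mtl-1 varied widely, at 15.0 ± 13.4, 10.2 ± 10.7, 22.6 ± 20.7 and 65.5 ± 50.2 CPM. The F-box gene fbxa-151 had no count in any CF1038 library against 2.86 ± 0.935 CPM in N2, at least 702-fold lower with a floor of 3 counts over the group (0.00407 CPM), a floor that covers counting error only. Further genes that were higher were scb-1 (log2 1.13, 36.6 ± 6.48 against 16.8 ± 1.36 CPM), clec-10 (1.11), nspc-18 (1.09), the protease gene asp-17 (1.08), dod-23 (1.05), the metallothionein gene mtl-2 (1.03), nspc-19 (0.98) and the noncoding RNA gene rncs-1 (0.98).

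The DAF-16 class I list gave 19 lower, 0 higher and 8 not passed out of 27 in CF1038 (21 adjusted over the list alone, median -0.83, camera adjusted p = 8.3e-28), and of the 39 lists it alone kept its call with an estimated correlation (adjusted p = 4.1e-05). It stayed lower with libraries 1 to 10, with libraries 11 to 20, with N2 libraries 21 to 30 and with the 6 time-course N2 libraries as controls (median -0.70 in the last). Its summed level was 2647 ± 481 CPM in CF1038 against 4455 ± 726 in N2, and lys-7 stood at 139 ± 54.2 against 601 ± 238 CPM. Class II genes gave 4 higher, 3 lower and 10 not passed out of 17 (camera adjusted p = 0.419), dod-23 and nuc-1 being higher and dod-19 (log2 -0.84) and dod-20 (-1.26) lower. Insulin signalling components gave 9 lower, 1 higher and 15 not passed out of 25 (9 and 2 adjusted over the list alone, median -0.02 and 0.06 with libraries 1 to 10, camera adjusted p = 4.2e-04, adjusted p = 0.372 with an estimated correlation), the kinase gene akt-2 falling by log2 -1.16. Insulin-like peptides gave 14 lower, 2 higher and 11 not passed out of 27 (14 and 2 adjusted over the list alone), with ins-24 at log2 -1.59. A median of -0.31, and -0.07 with N2 libraries 21 to 30 as controls, went with camera adjusted p = 3.6e-04 and adjusted p = 0.399 with an estimated correlation.

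Cytochromes P450 gave 37 lower, 2 higher and 30 not passed out of 69 (40 and 3 adjusted over the list alone), with cyp-35B1 at log2 -2.42. The median was -0.30, with camera adjusted p = 3.0e-08 and adjusted p = 0.175 with an estimated correlation. UDP-glucuronosyltransferases gave 34 lower, 2 higher and 28 not passed out of 64 (36 and 2 adjusted over the list alone), although ugt-64 was higher at 36.1 ± 2.54 against 18.5 ± 2.06 CPM. Its median log2 fold change was -0.27, with camera adjusted p = 2.5e-05 and adjusted p = 0.372 with an estimated correlation. Infection response genes gave 30 lower, 1 higher and 23 not passed out of 54 (33 and 1 adjusted over the list alone), with pals-26 at log2 -1.54 and pals-37 at -1.47. This list had a median of -0.32, and -0.12 and -0.11 with N2 libraries 21 to 30 and the time-course libraries as controls, with camera adjusted p = 5.0e-07 and adjusted p = 0.342 with an estimated correlation. Lysozymes and saposins gave 16 lower, 3 higher and 16 not passed out of 35 (18 and 3 adjusted over the list alone). Over the list the median was -0.26, with camera adjusted p = 2.3e-04 and adjusted p = 0.438 with an estimated correlation. Glutathione S-transferases gave 16 lower, 3 higher and 26 not passed out of 45, also adjusted over the list alone, with gsto-1 at log2 -1.12. Here the median stood at -0.17, and -0.04 with N2 libraries 21 to 30, with camera adjusted p = 0.00355 and adjusted p = 0.617 with an estimated correlation. Oxidative stress genes gave 13 lower, 5 higher and 17 not passed out of 35 (14 and 6 adjusted over the list alone). Across members the median was -0.10, with camera adjusted p = 0.0332 and adjusted p = 0.422 with an estimated correlation.

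Major sperm proteins gave 25 higher and 1 not passed out of 26 (25 adjusted over the list alone, median 1.05, camera adjusted p = 9.9e-15, adjusted p = 0.372 with an estimated correlation). Their summed level was 36.1 ± 14.2 against 17.7 ± 6.83 CPM, and it moved with library number. It was 45.49 ± 12.58 and 26.6 ± 8.24 CPM in CF1038 libraries 1 to 10 and 11 to 20, and 14.8 ± 4.35, 14.9 ± 5.35 and 23.5 ± 6.85 CPM in N2 libraries 1 to 10, 11 to 20 and 21 to 30. With N2 libraries 21 to 30 as controls 9 were higher of 27 (median 0.66). Other sperm genes gave 18 higher, 2 lower and 25 not passed out of 45 (20 and 3 adjusted over the list alone, median 0.18, camera adjusted p = 2.2e-04, adjusted p = 0.372 with an estimated correlation). Proteasome genes gave 30 higher and 1 not passed out of 31 (30 adjusted over the list alone), pbs-3 at 177 ± 15.1 against 149 ± 12 CPM, but 3 were higher with N2 libraries 21 to 30 and 2 with the time-course N2 libraries as controls. Their summed level also moved with library number. In libraries 1 to 10 it was 7068 ± 781 CPM in CF1038 against 5837 ± 682 in N2 (SD, n = 10). In libraries 11 to 20 it was 7858 ± 592 against 6547 ± 690 CPM, and in N2 libraries 21 to 30 it was 7098 ± 747 CPM. For this list the median was 0.20, with camera adjusted p = 8.1e-10 and adjusted p = 0.438 with an estimated correlation. The nuclear respiratory chain gave 37 higher, 5 lower and 21 not passed out of 63 (40 and 5 adjusted over the list alone). Its median was 0.13, with camera adjusted p = 2.9e-06 and adjusted p = 0.544 with an estimated correlation. Germline genes gave 23 higher, 1 lower and 29 not passed (25 and 1 adjusted over the list alone). Their median was 0.15, 0.00 with N2 libraries 21 to 30 (2 higher and 2 lower) and -0.07 with the time-course controls, with camera adjusted p = 4.7e-05 and adjusted p = 0.666 with an estimated correlation. Splicing factors gave 27 higher, 4 lower and 37 not passed (27 and 4 adjusted over the list alone). Their median was 0.08, with camera adjusted p = 0.00205 and adjusted p = 0.52 with an estimated correlation. Ribosomal proteins gave 17 higher and 63 not passed (15 adjusted over the list alone, median 0.06 and -0.03 with the time-course controls, camera adjusted p = 0.00335, adjusted p = 0.707 with an estimated correlation). Cell cycle genes gave 5 higher and 28 not passed (0 adjusted over the list alone). Their median was 0.07, with camera adjusted p = 0.021 and adjusted p = 0.698 with an estimated correlation. The mitochondrial respiratory chain gave 4 higher and 8 not passed (4 adjusted over the list alone). The median was 0.11, -0.02 with libraries 1 to 10 and -0.09 with the time-course controls, with camera adjusted p = 0.0441 and adjusted p = 0.666 with an estimated correlation.

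Collagens gave 45 lower, 3 higher and 113 not passed out of 161 (44 and 3 adjusted over the list alone, median -0.32, camera adjusted p = 0.00542, adjusted p = 0.698 with an estimated correlation), with a median of 0.26 against N2 libraries 21 to 30 and 0.47 against the time-course libraries. With libraries 1 to 10 and 11 to 20 of both strains it was -0.50 and -0.53. The summed collagen level ran from 4602 to 29840 CPM over CF1038 libraries and from 13052 to 28190 over N2 libraries. The lowest CF1038 library thus lay far below every N2 library. Hypodermal genes gave 10 lower and 22 not passed out of 32 (10 adjusted over the list alone, median -0.26, camera adjusted p = 0.017, adjusted p = 0.698 with an estimated correlation), with medians of 0.15 and 0.40 against N2 libraries 21 to 30 and the time-course libraries. Muscle genes gave 13 lower, 1 higher and 26 not passed (12 and 1 adjusted over the list alone, median -0.22, and 0.02 against libraries 21 to 30, camera adjusted p = 0.0112, adjusted p = 0.698 with an estimated correlation). The summed muscle level ran from 3282 to 8839 CPM over CF1038 libraries and from 4821 to 10097 over N2 libraries. Heat shock genes gave 7 lower, 1 higher and 16 not passed (7 and 1 adjusted over the list alone, median -0.19, and 0.05 and 0.20 against N2 libraries 21 to 30 and the time-course libraries, camera adjusted p = 0.0166, adjusted p = 0.497 with an estimated correlation), with hsp-70 at log2 -0.96. Neuronal genes gave 19 lower, 1 higher and 29 not passed (22 and 1 adjusted over the list alone, median -0.25, and 0.02 and -0.03 against the same 2 sets of controls, camera adjusted p = 0.00395, adjusted p = 0.666 with an estimated correlation). Carbon metabolism gave 18 lower, 8 higher and 17 not passed (18 and 8 adjusted over the list alone), pck-2 at log2 -0.86. Its median was -0.07, with camera adjusted p = 0.0254 and adjusted p = 0.617 with an estimated correlation. Lipid metabolism gave 32 lower, 17 higher and 52 not passed (32 and 19 adjusted over the list alone), acs-17 at log2 -1.07. Its median was -0.06, and 0.04 with libraries 1 to 10, with camera adjusted p = 0.0423 and adjusted p = 0.666 with an estimated correlation.

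The camera test did not pass in CF1038 for flp genes (4 lower of 30, adjusted p = 0.0533), basement membrane (7 lower of 17, adjusted p = 0.0673) and organelle chaperones (11 lower and 7 higher of 23, adjusted p = 0.0853). It did not pass for other somatic tissues (13 and 2 of 21, adjusted p = 0.142), histones (2 and 10 of 55, adjusted p = 0.168) and antimicrobial peptides (11 and 7 of 40, adjusted p = 0.175). The same holds for C-type lectins (35 lower and 46 higher of 147, adjusted p = 0.246), vitellogenins (0 and 1 of 6), intestinal genes (8 and 6 of 33) and pharyngeal genes (6 and 0 of 30), the last 3 with adjusted p = 0.419. With the time-course controls pharyngeal genes had 1 lower and 12 higher. F-box genes (62 and 45 of 350, adjusted p = 0.544), embryo genes (2 and 1 of 22, adjusted p = 0.726) and autophagy genes (20 and 15 of 80, adjusted p = 0.762) did not pass either. Among their members, abf-2, which encodes an antibacterial factor, was lower by log2 -2.52, the linker histone gene hil-1 by -1.77 and the esterase gene ges-1 by -1.15, and aqp-8 was higher by 0.97. The median of antimicrobial peptides was -0.10, and 0.35 and 0.42 against N2 libraries 21 to 30 and the time-course libraries. The count of differing genes was 10274 with a replicate block, 9775 with library number as a covariate, 3477 with the 6 time-course N2 libraries and 2875 with N2 libraries 21 to 30 as controls. Fitted apart, libraries 1 to 10 and 11 to 20 of both strains gave 6707 and 5825 genes of 15577, of which 4220 were shared in the same direction and 1 in the opposite, with 1251 expected if independent.

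The 2 N2 sets at day 6 carry the same strain, age and treatment in the labels. The genes differing between the 2 N2 day 6 sets numbered 3142 of 16703, with 2055 higher and 1087 lower in the second set. The cuticle collagens col-109 (11.5 ± 8.71 against 1.78 ± 0.850 CPM, log2 2.68, SE 0.67, adjusted p = 0.00799, n = 30 and n = 6) and dpy-3 (2.01) and the insulin-like peptide gene ins-19 (2.31) were higher in the second set, and the collagens col-124 (-1.08) and col-129 (-1.07) and the lectin gene clec-86 (-1.06) were lower. With libraries 1 to 10 of the second set the count was 8726, and with libraries 21 to 30 edgeR called 0 genes, while 2471 had an unadjusted p under 0.05.

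Whether genes that change with age also differ in CF1038 was tested over the 15736 genes in both comparisons, which share no library. Genes lower at day 18 and lower in CF1038 numbered 1124 against 978 expected (odds ratio 1.3, Fisher's exact p = 5.6e-10), and genes higher in both 618 against 733 (odds ratio 0.763, exact p = 3.4e-08). Those lower at day 18 and higher in CF1038 numbered 983 against 850 (odds ratio 1.3, exact p = 2.3e-09), and those higher at day 18 and lower in CF1038 833 against 844 (odds ratio 0.978, exact p = 0.637). Across genes, the log2 fold changes had a Pearson r of 0.17 and a Spearman rho of 0.08. The overlap of genes higher in both turned with the threshold: among genes that also changed at least 2-fold, 51 were higher in both against 11.4 expected (odds ratio 7.40) and 100 lower in both against 31.2 (odds ratio 4.82). The pairs of opposite direction also exceeded the expected count, with 30 lower at day 18 and higher in CF1038 against 14.1 (odds ratio 2.54, exact p = 4.6e-05) and 38 higher at day 18 and lower in CF1038 against 25.2 (odds ratio 1.61, exact p = 0.0106). Close copies that share reads, such as the major sperm protein genes that were higher in both comparisons, count as separate genes here. The odds ratios also moved with the controls. In a test chosen after the data were seen, the 6 time-course day 6 libraries were split by odd and even number, so that day 18 and CF1038 shared no control. Genes higher in both then had odds ratios of 0.670 and 2.27, and genes lower at day 18 and higher in CF1038 2.22 and 0.665. Genes lower in both had 1.45 and 1.86, and genes higher at day 18 and lower in CF1038 0.783 and 0.565. Genes higher at day 11 and lower in CF1038 numbered 1341 against 754 expected (odds ratio 3.09, exact p = 1.9e-150). Genes lower at day 11 and higher in CF1038 numbered 1171 against 604 (odds ratio 3.45, exact p = 6.2e-161). The overlaps of days 8, 11 and 14 were added after the data were seen. At day 14 the same pairs of directions had odds ratios of 2.61 and 3.84, and at day 8 they had 2.52 and 1.12, the last one not passing (exact p = 0.163). Pairs of the same direction, higher and then lower, had 0.633 and 0.763 at day 8, 0.455 and 0.382 at day 11, and 0.420 and 0.374 at day 14. At days 8, 11 and 14 the Pearson r was 0.03, -0.06 and 0.03 and the Spearman rho -0.04, -0.21 and -0.20. The overlaps of these ages were run only with the second N2 set as the controls of CF1038. Whether they move with the controls was not tested. In that set, the change toward higher library numbers had a rho of 0.437 with CF1038, and 0.304 where no library was shared. With the changes at days 8, 11 and 14 its rho was 0.127, -0.11 and -0.12. What this number pattern adds to the overlaps was not tested. The genes lys-7, dod-3 and col-183 rose by day 11 and stood lower in CF1038.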

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

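In this part, the tests of larval genes, of the spe genes and of a shift toward day 8, and the comparisons of the number pattern with other changes, were chosen after the result was seen. In 20 of 165 groups of 6 libraries the highest or lowest library lay far from the other 5 for its range, and chance gives about 1 in 20 groups. At day 6 these were the total count of library 4 (41 in units of 1e+06), cld-1 and dod-21 in library 5 (19.89 and 43.39 CPM), nspc-16 in library 5 (24.84 CPM), msrp-3 in library 3 (0.07443 CPM), nsph-4.2 in library 2 (1.271 CPM), col-109 in library 1 (3.111 CPM) and, below the others, spc-2 in library 4 (0.2442 CPM). At day 8 they were cld-1 and dod-21 in library 5 (251.4 and 319.9 CPM), lact-6 in library 4 (2.543 CPM) and ugt-43 in library 3 (45.87 CPM). At day 11 library 3 stood out for col-17, pud-1.2 and pud-2.2 (1.162, 78.22 and 33.8 CPM). At day 14 they were col-17 and pud-1.2 in library 6 (0.5618 and 13.41 CPM) and col-167 in library 5 (1.571 CPM), and at day 18 col-17 in library 2 (0.2898 CPM) and col-117 in library 5 (1.755 CPM).

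Sperm genes were higher at day 18 than at day 6. Reads shared among near-identical copies are argued against as the whole source, since the spe genes had a median log2 fold change of 2.97, with 26 of 28 higher. Larvae of a next generation are argued against by the moulting genes, whose median was -0.24 with 2 higher and 6 lower of 16. More males among the worms stay open: the tested genes of male-specific neurons had a median of 0.33, under the bound of 1 set for excluding males. That bound was wrong for genes this near the floor, since 4 of 7 could be tested and stood at 0.26 to 0.99 CPM at day 6, a judgement made after the result was seen. A change of sperm content or of its RNA with age in these worms may also explain the pattern and was not tested.

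In the second N2 set, libraries 21 to 30 differed from libraries 1 to 10 in 8829 of 15762 genes, 4370 higher and 4459 lower, although the labels give them 1 description. With the percent of ribosomal RNA as a covariate 99.6 percent of these calls remained, and with depth 95.4 percent, which argues against both as the whole source. A shift along the change from day 6 to day 8 stays open, with a Spearman rho across genes of 0.127, between the bounds of 0.1 and 0.3 set for it, against -0.11, -0.12 and 0.03 with the changes from day 6 to days 11, 14 and 18. With the change in CF1038 the rho was 0.437, from the same N2 libraries, and 0.304 with N2 libraries 11 to 20 as the controls, where no library is shared. Some lists moved as in CF1038: collagens gave 103 lower and 18 higher of 160, muscle 32 lower of 40 and proteasome 25 higher of 31. Others ran the other way, such as DAF-16 class I genes (12 higher and 6 lower of 26) and cytochromes P450 (34 higher and 9 lower of 68). What the number pattern has in common with the strain change was not tested further. Libraries with neighbouring numbers resembled each other in N2 (mean r of 0.310 against -0.0827 for the rest) and in CF1038 (0.244 against -0.121), each with a permutation p of 1e-04, the smallest that 10000 permutations can give. The labels give no batch that differs, so a batch that follows the number may be the source and cannot be told apart from the order of collection.

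In CF1038, 11 genes were at least 16-fold lower than in N2, among them col-183, spp-27, clec-15, F17B5.1 and fbxa-151. Of these, 2 lay within 100 kb of another (F56D6.9 and F56D6.8, permutation p = 0.117), and 1 lay within 2 Mb of daf-16 (1-sided exact p = 0.387, odds ratio 2.20 with an upper limit of 15.5). Deleted or divergent stretches of the CF1038 genome, and linkage to daf-16, cannot be told apart from an effect of daf-16 with so few genes. A loss of expression without daf-16 may hold for some of them and was not tested here, since CF1038 is the 1 mutant strain in the data.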

How the results depend on the processing

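In this part, the fits of libraries 1 to 3 and 4 to 6, of subsets of the second N2 set, and with library number as a covariate were chosen after the data were seen. Of the values for whole comparisons, 79 planned and 24 added ones kept their direction and their side of the threshold, or stayed within 1.5 times, and the rest are given here. A turned direction was counted as kept for whole comparisons where neither value passed, and for named genes where the main value had not passed. For named genes, 737 planned and 323 added values kept both, 3 planned and 17 added ones were no longer past the threshold, 1 came past it, and 0 reversed in the edgeR and DESeq2 fits run. Of those no longer past it, 8 came with libraries 4 to 6 alone and 6 with N2 libraries 21 to 30 in the comparison of the 2 N2 sets, and both settings compare fewer libraries.

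The count of genes changed at day 8 went from 1950 to 3805 with the 12 libraries alone, 3837 with libraries 1 to 3, 523 with libraries 4 to 6 and 7979 with 36 controls. With libraries 4 to 6 the day 11 count went from 7338 to 4557 and the count from day 8 to day 11 from 4951 to 2336. The count from day 11 to day 14 went from 2443 to 1494 with the 12 libraries and 6131 with libraries 1 to 3. The count between the strains went from 6238 to 10274 with the replicate block on libraries 1 to 20 of each strain, 9775 with library number as a covariate, 3477 with the 6 time-course N2 libraries and 2875 with N2 libraries 21 to 30. The count of genes differing between the 2 N2 day 6 sets went from 3142 to 8726 with libraries 1 to 10, and to 0 with libraries 21 to 30 in edgeR, where 2471 genes had an unadjusted p under 0.05; DESeq2, run on all libraries, called 3461. Some of these settings compare fewer libraries, but counts went up as well as down with fewer, and the cause was not tested.

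The wider spread at day 14 passed with genes at 10 CPM or more (difference 0.191, adjusted p = 0.0173) and with 1 minus the Spearman correlation (0.00689, adjusted p = 0.0173), and not with a prior count of 0.5 (0.1, adjusted p = 0.251). The differences of days 8, 11 and 18 passed in no setting. With a prior count of 0.5 they turned direction, at 0.0246, -1.96e-04 and -0.0187. That of day 11 also turned with genes at 10 CPM or more, at -0.0017. For day 18 and CF1038, the odds ratio of genes higher in both reversed from 0.763 to 7.40 with a 2-fold threshold and to 1.46 with shared controls, and that of genes lower at day 18 and higher in CF1038 from 1.3 to 0.972 with shared controls. The odds ratio of genes higher at day 18 and lower in CF1038 came past the threshold at 1.61 with the 2-fold threshold, 0.617 with shared controls and 0.883 with library number as a covariate. The setting with shared controls replaced 30 controls by 6 others. Simulated groups with no change and shared controls had an r of 0.63 ± 0.0237 (SD, n = 10 simulations) and 0 genes called in both, so they give no odds ratio to set beside these. No effect of daf-16 is read from that shift, and its cause was not tested. With an estimated correlation, 0, 0, 0, 1 and 1 lists passed at days 8, 11, 14, 18 and in CF1038, against 10, 16, 12, 18 and 25 with the preset one.

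With the replicate block, the counts at days 8, 11, 14 and 18 were 2138, 7515, 9687 and 9711, and 2663 from day 11 to day 14. The pairing by number that the block assumes had little to show for it in the time course, where libraries of the same number and different age had a median r of 0.0451, and more between the strains (0.270, with 15 of 20 above 0.1), where 10 of 40 libraries were closest to their own number. At 34.4 or more counts per library in units of 1e+06, depth limits genes near the floor: col-92 had 6 counts in all at day 18, and folds of such genes are uncertain.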

Other observations

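All the counts of other splits in this part were planned, except that of day 18 against day 6, the fits by libraries 1 to 3 and 4 to 6, and the splits by number, tests chosen after the result was seen. In 100 splits of the same libraries, fitted alone, the real one included, no other split drawn called as many genes as the real one, with 1 split as large, the real one. In 7 of 10 comparisons this argues against chance at the level of 1 split in 100, for independent libraries only. The labels do not say that libraries are independent, and those of days 14 and 18 lay apart by number. So chance is not taken as excluded in these 7. In the 3 others, from day 11 to day 14, CF1038 and the 2 N2 sets, a split by number called more genes than the real one. The real count and the highest other were 3805 and 823 for day 8, 8285 and 1 for day 11, 7398 and 1249 for day 14, 10166 and 0 in edgeR for day 18, 6258 and 22 from day 8 to day 11, 6467 and 3808 from day 14 to day 18, 8999 and 1096 for the trend, 6238 and 1 for CF1038, and 3142 and 38 for the 2 N2 sets. From day 11 to day 14 the real count was 1494 and the highest of the splits drawn 24, but the split of libraries 1 to 3 against 4 to 6 of both ages, not drawn, called 2275, more than the real one. This points to a structure of the libraries by number, so chance is not taken as excluded for this comparison. In 6 of the other comparisons of ages this split called 37 genes or fewer, and for the trend it was not run, so a structure by number stays unchecked there. These fits left the difference between the ages in the spread, so a low count does not show that such a structure is absent. At days 14 and 18 libraries 1 to 3 and 4 to 6 lay apart on the principal components. For CF1038, libraries 1 to 10 of both strains against the others, 20 against 30, called 7759, more than the 6238 of the real split. For the 2 N2 sets, libraries 1 to 6 of the second set against the others, 6 against 30, called 8705, more than 3142. From these 2 counts alone, chance is not taken as excluded either. Within libraries 1 to 3 and 4 to 6 the counts from day 11 to day 14 were 6131 and 2087, and with a block of 2 levels for these subsets 2926. For CF1038 the count with the replicate block was 10274, and libraries 1 to 10 and 11 to 20 fitted apart gave 6707 and 5825, of which 4220 were shared in the same direction and 1 in the opposite. If independent, 1251 would be shared, and the log2 fold changes of the 2 fits had a Pearson r of 0.85. These values argue against chance for the shared genes, although genes are not independent replicates. For the 2 N2 sets the count was 8726 with libraries 1 to 10 of the second set and 0 in edgeR with libraries 21 to 30.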
